A study of Homo sapiens with 4 samples.

How the data were processed

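Total RNA from cultured human dermal fibroblasts, the matrix-producing cells of the skin, was measured on 4 arrays with biotin-labelled cRNA made by the Affymetrix protocol, per the labels. Each array was 1 group: sham, interleukin-1α (IL-1α) alone, ultraviolet B (UVB) alone, and UVB with IL-1α. The UVB array's title gives 30MJ, read here as 30 mJ/cm2, and the series text gives 1 ng/mL for IL-1α. The doses of the co-treated array and the time between treatment and harvest on the arrays were not given in the sources used here.

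The deposited values are log2 expression values per probe set, 1 column per array. The authors made them with RMA, which corrects background, normalizes between arrays and summarises probes, per the submitters' processing notes, which name no version. The distributions of the deposited log2 values were alike, with array medians between 7.07 and 7.12 and all values between 3.02 and 14.8. Values on this scale flatten near background, so differences of dim genes are understated. The precision of every comparison is limited by the number of arrays, which is 1 per group.

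The table held 1259 probe sets, of which 1069 carried a RefSeq accession. Accessions were matched without versions to a RefSeq gene table of assembly GRCh38.p14, used for names only. A symbol was found for 1043 probe sets of 927 genes, and no probe set had several symbols. The other 216 probe sets stayed unnamed, 26 of them with an accession that did not match and 190 with other identifiers. IL6 and TNF had no named probe set and were not analysed here. Of the named probe sets, 70 were of the type that can share signal with other genes and 212 of the type that can cover several transcripts, by the ending of their identifier. A gene was represented by its probe set with the highest mean over the 4 arrays, which was a choice among several for 93 genes. A gene was tested if its highest log2 value was at least 6, which left 680 genes and set aside 247.

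For each pair of groups, the difference of log2 values was taken per gene, and genes with a difference of at least 1 (2-fold) were counted in each direction. With 1 array per group these counts have no replicate check and no p-value. The non-additive term was the UVB with IL-1α value minus the IL-1α value, minus the UVB value, plus the sham value. Being taken on log2 values, it is 0 where the fold changes of the 2 treatments multiply. Each treatment has a pair of contrasts that share no array: IL-1α against sham beside UVB with IL-1α against UVB, and UVB against sham beside UVB with IL-1α against IL-1α. Their mean is called the mean IL-1α or mean UVB difference. The only test was limma's moderated two-sided test of each treatment in an additive model over all 4 arrays, 2 against 2, with Benjamini-Hochberg adjustment over the 680 genes and a threshold of 0.05. Its 1 residual degree of freedom per gene is the non-additive term. The labels do not show more than 1 culture per group. These p-values therefore set each effect against the departure from additivity between these arrays and not against the spread between cultures. A gene whose response to a treatment depends on the other treatment is penalised. The test was tested on simulated data with additive effects on 200 of 680 genes for the UVB comparison, in 20 rounds. It called 84.1% of genes simulated with a 1.5-fold change, 95.4% at 2-fold and 98.5% at 4-fold, and 3.67% of its calls were false. The simulated noise followed the prior variance that limma fitted to these arrays. These shares therefore hold for additive effects only and do not describe genes with a non-additive response or the spread between cultures.

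The design, the lists, the rule for named genes and the alternatives were fixed before the data were examined, except where stated. Genes were named by this rule. For each treatment, up to 12 genes per direction with the largest mean difference were taken among tested genes at least 2-fold different the same way in both contrasts. For the non-additive term, the 6 highest and the 6 lowest genes with an absolute value of at least 1 were taken. CHSY1, CHSY3, CHPF, CSGALNACT1, CSGALNACT2, SRGN, VCAN, DCN, BGN, HAS1, HAS2, HAS3, TNF, IL6, CXCL8 and ICAM1 were always included where measured, with up to 4 members of each list by absolute mean difference. Genes named outside this rule were chosen after their values were seen, as the text says.

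The 34 lists covered chondroitin sulfate (CS) chain polymerisation; CS and dermatan sulfate (DS) sulfation and epimerisation; linker synthesis of glycosaminoglycans (GAGs); heparan sulfate (HS) synthesis; hyaluronan; core proteins of CS and DS, keratan sulfate (KS) and HS proteoglycans; GAG and glycan degradation; sugar nucleotide and sulfate donor supply; sialyltransferases; fucosyltransferases; N-glycan assembly; O-GalNAc glycans; galactosyl- and N-acetylglucosaminyltransferases; galectins, siglecs, C-type lectins and mucins. Others covered the Notch pathway, chemokines, interleukins and inflammatory cytokines, cytokine receptors, growth factors and their receptors, adhesion molecules, matrix proteins and metalloproteinases, p53 and DNA damage response, reference genes, and markers of fibroblasts, keratinocytes, endothelial cells, leukocytes and melanocytes. The median difference of a list with at least 4 tested genes was given as a percentile among 10000 random lists of the same size drawn from the same deciles of mean expression, as a description of these arrays and not a test. Of 40 unshifted simulated lists, 1 fell outside the central 95%, which spans percentiles 2.5 to 97.5. Calls were also counted with p-values adjusted over the list alone. That adjustment works within a list and does not correct across the 34 lists.

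The alternatives were expression floors of 5, 7 and none; arrays centred on their medians; cyclic loess or quantile normalization between arrays; the mean of a gene's probe sets or every probe set on its own; size thresholds of 1.5-fold and 3-fold; and limma with a trended, robust prior or without the other treatment. The lists were fixed beforehand, but the calls adjusted over each list alone, as deposited and under the 3 scalings, were not part of the fixed design and were added after seeing the data. Raising values below the floor to it, so that a fold against them is a lower bound, was also chosen after seeing the data. R 4.3.3, limma 3.58.1, matrixStats 1.5.0, Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used.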

Results

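Messenger RNA of cultured human dermal fibroblasts was compared across 4 conditions in a factorial layout: sham treatment, IL-1α, UVB at 30 mJ/cm2, and UVB together with IL-1α. The array held 927 named genes, mainly of glycan synthesis, glycan-binding proteins, cytokines and growth factors. The design asked how sunburn-type radiation and an inflammatory cytokine, alone and together, affect transcripts of the enzymes and core proteins of glycosaminoglycans and proteoglycans. Each condition was measured on 1 array, so single differences have no replicate error, and 680 genes were bright enough to be counted. Across probe sets, Pearson's r between arrays lay between 0.984 and 0.995.

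IL-1α without UVB was accompanied by much higher transcripts of chemokines and cytokines. CXCL2 was 21.0-fold, CXCL3 18.3-fold and CXCL1 3.56-fold above sham, all of them neutrophil attractants whose sequences are similar enough that their signals may not be fully separate. CCL20, which attracts lymphocytes and dendritic cells, had a log2 value of 10.32 against 5.77 in sham, which is below the expression floor of 6, so it stood at least 4.32 above sham on the log2 scale. IL1A itself was 19.1-fold higher, CSF2, a growth factor of myeloid cells, 18.4-fold, LIF 7.52-fold and IL1B 5.08-fold, and the leukocyte adhesion molecules VCAM1 and ICAM1 were 6.50-fold and 2.80-fold higher. In all, 28 genes were at least 2-fold higher and 2 at least 2-fold lower, namely BMP4, a bone morphogenetic protein, at a log2 difference of -1.22 and EXTL1, a heparan sulfate glycosyltransferase homologue, at -1.04. Of the 28, 5 had a sham value below the floor, and 27 were still at least 2-fold higher with such values raised to the floor.

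After UVB, IL-1α was again accompanied by higher chemokine transcripts, with smaller fold changes. CCL20 stood 13.4-fold above the UVB array, CXCL3 11.1-fold, CXCL2 8.90-fold, CSF2 4.36-fold, IL1A 3.67-fold, CXCL1 3.03-fold and IL1B 2.03-fold, and CXCL6 and CXCL5, relatives of CXCL1, were both higher by 1.02 on the log2 scale. These 9 genes were at least 2-fold higher after UVB, each was also at least 2-fold higher without UVB, and none was 2-fold lower. Independent lists of those lengths would share 0.371 genes. The IL-1α dose of the co-treated culture is not given, so a weaker stimulus there cannot be ruled out. Of the 28 genes higher without UVB, 24 lay above 0 after UVB, with a median log2 difference of 0.52 against 1.90 without UVB.

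Chemokines as a list had a median mean IL-1α difference of 0.85 over 27 tested genes, at percentile 100 of matched random lists, and 24 of them lay above 0. The array held 38 chemokines, and the floor favours those that IL-1α raised. CCL1, CCL3 and CCL11, named after their values were seen, reached it only on arrays with IL-1α. Interleukins and inflammatory cytokines had a median of 1.67 over 7 genes, also at percentile 100, with LIF, CSF2, IL1A and IL1B at least 2-fold higher on average. In the additive limma test 0 genes were called for IL-1α over all genes tested (smallest adjusted p = 0.107), while 72 had an unadjusted p below 0.05, 24 higher and 48 lower. That split goes with a small offset of the arrays, since 34.0% of all tested genes had a mean IL-1α difference above 0. The median over these genes was -0.05 as deposited and 0.01 after cyclic loess. Adjusted over the list alone, 9 chemokines rose and 0 fell, CXCL1, CXCL2, CXCL3, CXCL5, CXCL6, CXCL8 and CCL20 among them, and the count was 5 after cyclic loess, 6 after quantile normalization and 15 with centred arrays. Adjusted over the list alone, 0 genes of any other list were called for IL-1α. Across genes, which are not independent replicates, the 2 IL-1α contrasts correlated with Pearson's r of 0.782 and Spearman's rho of 0.523.

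**Figure D1:**
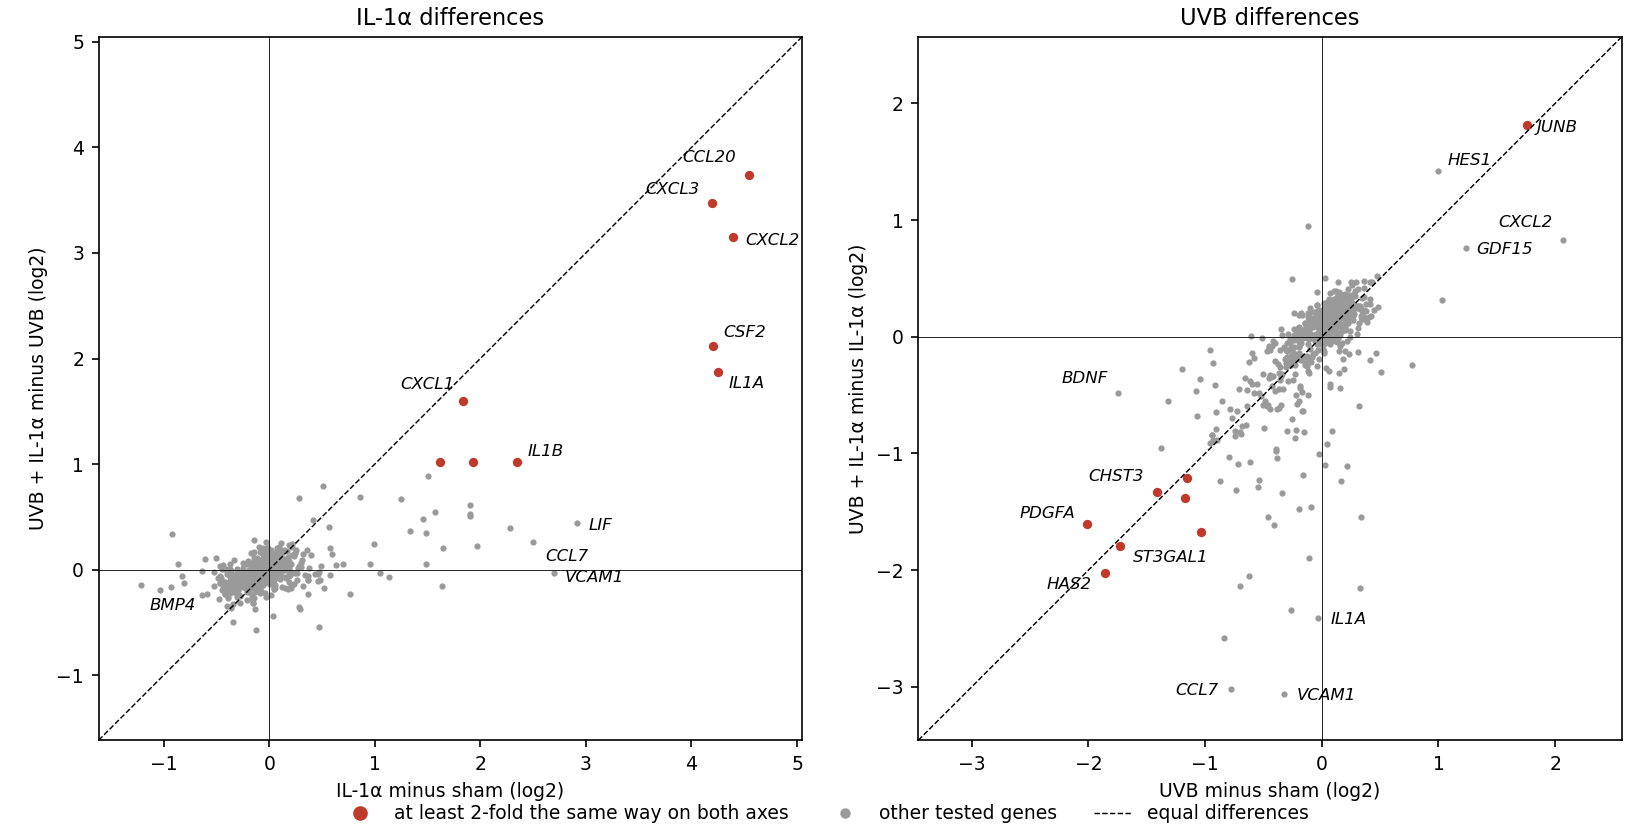
Log2 differences of 680 genes, each point a gene, with IL-1α minus sham (x axis) against UVB with IL-1α minus UVB (y axis) on the left and UVB minus sham (x axis) against UVB with IL-1α minus IL-1α (y axis) on the right, red points being at least 2-fold different the same way on both axes. On the left the 9 red genes lie below the dashed line of equal differences, CXCL3 at 4.19 and 3.48; on the right 7 red genes lie low, HAS2 at -1.86 and -2.02, and JUNB lies high at 1.76 and 1.81.

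In the additive test of the deposited values, the genes lower on the UVB arrays included single enzymes that build or sulfate sugar chains and single receptors. HAS2, a hyaluronan synthase, fell by 1.94 on the log2 scale over both backgrounds (SE 0.0728, adjusted p = 0.0293 by limma), and ST3GAL1, a sialyltransferase, fell by 1.76 (SE 0.0591, adjusted p = 0.0293). The chondroitin sulfotransferases CHST3 and CHST15 fell by 1.37 (SE 0.0615, adjusted p = 0.037) and 1.28 (SE 0.0818, adjusted p = 0.047). IL4R, the interleukin-4 receptor chain, fell by 1.19 (SE 0.0581, adjusted p = 0.0386) and BMPR2, a bone morphogenetic protein receptor, by 0.91 (SE 0.0575, adjusted p = 0.047). JUNB, a transcription factor of the AP-1 family, rose by 1.78 (SE 0.0582, adjusted p = 0.0293). Each of these 7 genes differed in the same direction with and without IL-1α. The test favours such genes, because its residual is the difference between the 2 UVB contrasts, so this is no separate support.

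Over all genes tested, limma called 9 genes for UVB, 1 higher and 8 lower, among 210 with an unadjusted p below 0.05 (103 higher and 107 lower). The remaining calls, FZD7, a Wnt receptor, and TARDBP, an RNA-binding protein, fell by 0.94 and 0.89 (adjusted p = 0.047 for both) and were named after their values were seen. The calls depended on how the arrays were scaled: 0 genes passed after cyclic loess, where the adjusted p of the 7 genes named by the rule lay between 0.0734 and 0.0805, and 0 passed after quantile normalization, where it lay between 0.0834 and 0.0961. Centring each array on its median gave 222 calls, 161 higher and 61 lower, a setting that moved the median mean UVB difference of all genes from 0.07 to 0.22. The log2 differences themselves kept their direction under each of these 3 scalings, from -1.79 to -1.97 for HAS2 and from 1.76 to 1.93 for JUNB. With 210 of the 680 tested genes at an unadjusted p below 0.05, calls adjusted over a list alone need not set that list apart.

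By size alone, UVB against sham left 14 genes at least 2-fold lower and 4 at least 2-fold higher (10 and 5 with centred arrays, 9 and 5 after quantile normalization). PDGFA, a platelet-derived growth factor chain, was 4.02-fold lower, HAS2 3.63-fold, BDNF, a neurotrophin, 3.35-fold and ST3GAL1 3.31-fold lower. Higher were CXCL2 (4.19-fold), JUNB (3.38-fold), GDF15, a stress-responsive member of the TGF-β family (2.35-fold), and CXCL3 (2.04-fold). In the presence of IL-1α, 35 genes were at least 2-fold lower and 2 at least 2-fold higher with UVB, the higher ones being JUNB and HES1, a Notch target. All 14 genes lower without IL-1α also lay below 0 with it, and 7 were at least 2-fold lower in both backgrounds, namely HAS2, PDGFA, ST3GAL1, CHST3, FUT4, CHST15 and IL4R, where independent lists would share 0.721 genes. JUNB was the gene at least 2-fold higher in both, and the split was 6 lower and 2 higher with centred arrays and 5 lower and 2 higher after quantile normalization. Across genes, which are not independent replicates, the 2 UVB contrasts correlated with Pearson's r of 0.646 and Spearman's rho of 0.714. Handling that followed UVB across the arrays cannot be separated from UVB.

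Growth factors had a median mean UVB difference of -0.37 over 29 tested genes, at percentile 0.01 of matched random lists, and of -0.19 with centred arrays and -0.24 after quantile normalization. Over all genes tested 0 of them were called, and adjusted over the list alone 8 fell and 3 rose, PDGFA and FGF5, a fibroblast growth factor, among the fallen and GDF15 among the risen. These list counts were 5 and 1 after cyclic loess, 6 and 1 after quantile normalization and 9 and 9 with centred arrays. As deposited they included FGF7 among the fallen and FGF19 among the risen, both near the floor and named after their values were seen. With values below the floor raised to it, their mean UVB differences were -0.03 and 0.16. Growth factor receptors had a median of -0.19 over 14 genes, at percentile 3.84, with 12 below 0, and the median was -0.04 with centred arrays and -0.10 after quantile normalization. Adjusted over the list alone 5 receptors fell, BMPR2, IGF1R, PDGFRA and TGFBR1 among them, against 1 over all genes tested, and the counts were 7 lower after cyclic loess, 2 lower and 1 higher after quantile normalization, and 4 lower and 2 higher with centred arrays. The 4 tested genes of the fixed list of cytokine receptors and IL-1 signalling, IL4R, IL7R, IL17RA and OSMR, fell when adjusted over the list alone (1 over all genes tested), with a median of -0.60 at percentile 2.27 (2.65 with centred arrays); the list count was 5 after cyclic loess, 3 after quantile normalization and 4 with centred arrays. Some cytokine receptors outside that list were higher, EPOR, CSF3R and IL12RB1 having mean UVB differences of 0.31, 0.25 and 0.23, and were named after their values were seen. Interleukins and inflammatory cytokines had a median difference of 0.20 for UVB against sham (percentile 98.4, 5 of 7 above 0) and of -1.11 in the presence of IL-1α (percentile 0, 6 of 7 below 0), so their mean UVB difference of -0.45 at percentile 0.2 describes neither; without IL-1α the percentile was 94.9 after cyclic loess and 95.8 after quantile normalization. Chemokines had a median of 0.18 for UVB against sham (percentile 100, 22 of 27 above 0) and of -0.04 in the presence of IL-1α (percentile 0.46), the latter of a sign that turned with centred arrays, and their mean UVB difference was 0.10 at percentile 71.1 with a sign that depended on the scaling. Adjusted over the list alone, 0 genes of these 2 lists were called for UVB.

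The study asked about chondroitin sulfate synthases and chondroitin sulfate proteoglycans. CHSY1, a chondroitin sulfate synthase, had log2 values of 9.80 in sham, 9.75 with IL-1α, 8.90 with UVB and 9.10 with both, so it was 46.6% lower with UVB and 38.6% lower with both than in sham. CHSY3, another synthase, lay below the expression floor on every array, between 5.51 and 5.81, and CSGALNACT1, which starts the chain, between 5.40 and 5.56, so neither was compared. CHPF, a polymerising factor, differed little with UVB, at a mean difference of -0.04 that turned sign under another scaling. SRGN, which encodes the proteoglycan serglycin, was 1.28-fold above sham with either treatment alone and 1.45-fold above sham with both, at log2 values of 10.15, 10.51, 10.51 and 10.69.

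Over the 4 tested genes of chondroitin sulfate polymerisation the median mean UVB difference was -0.40, at percentile 5.72 (-0.25 with centred arrays and -0.26 after quantile normalization), and all 4 lay below 0 as deposited. In limma 0 were called over all genes tested (CHSY1 adjusted p = 0.079), and adjusted over the list alone 3 fell, CHSY1, CHPF2 and CSGALNACT2, a count that was 3 after cyclic loess, 1 after quantile normalization and 2 with centred arrays. The sulfation and epimerisation list had a median of -0.20 over 8 genes at percentile 10.3 (-0.05 with centred arrays and -0.03 after quantile normalization), and CHST3 and CHST15 fell both over all genes tested and adjusted over the list alone. Among linker enzymes XYLT1, a xylosyltransferase that starts the chain on the core protein, fell adjusted over the list alone (log2 difference -0.78, adjusted p = 0.0525 over all genes tested). The linker list's median over 6 genes was -0.04, with a sign that depended on the scaling. For IL-1α the median mean differences were -0.09 for polymerisation and -0.06 for sulfation, both of a sign that depended on the scaling, and -0.18 for linker synthesis with 6 of 6 genes below 0. The linker median was -0.15 with centred arrays and -0.07 after cyclic loess. As deposited it lay within the central 95% of matched random lists. Of all tested genes, 34.0% had a mean IL-1α difference above 0, so 6 of 6 below 0 need not set this list apart.

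Core proteins of chondroitin and dermatan sulfate proteoglycans went in different directions with UVB. Versican (VCAN) had a mean UVB difference of -0.42 and a mean IL-1α difference of -0.36, and was 42.1% lower with both treatments than in sham. Decorin (DCN) had a mean UVB difference of 0.37. Biglycan (BGN) had -0.14, a value that turned sign with centred arrays. ESM1, the endocan core protein, was at least 3.22-fold above sham with IL-1α and at least 1.16-fold with both treatments, its sham value lying below the floor. The 12 tested core proteins had a median mean UVB difference of 0.13 at percentile 90.0, which was 0.03 at percentile 30.3 after quantile normalization, 0.03 at 75.7 after cyclic loess and 0.28 at 86.1 with centred arrays, and in limma 0 of them were called over all genes tested or adjusted over the list alone, for either treatment.

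**Figure D2:**
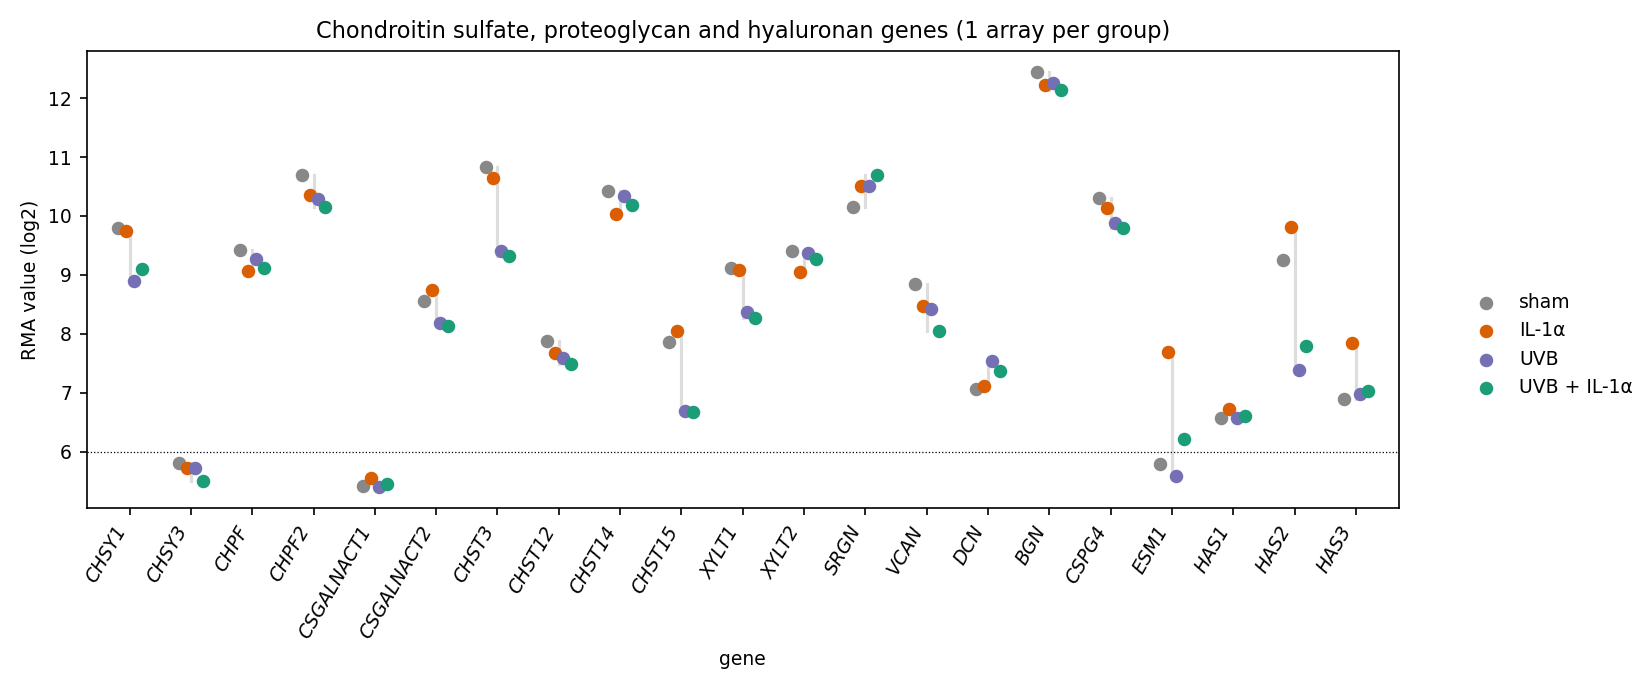
Log2 RMA values of genes for chondroitin sulfate synthesis, proteoglycan core proteins and hyaluronan synthases on the y axis, genes on the x axis, with 1 point per array coloured by group and a dotted line at the expression floor of 6. The UVB arrays lie low for CHST3, CHST15 and HAS2 (7.39 and 7.79 against 9.25 in sham), and CHSY3 and CSGALNACT1 lie below the floor on all 4 arrays.

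Heparan sulfate synthesis genes had a median mean UVB difference of -0.23 over 15 genes, at percentile 3.3, which was -0.08 at percentile 1.96 with centred arrays, -0.27 at 1.93 after cyclic loess and -0.14 at 1.61 after quantile normalization. In limma 0 were called over all genes tested, and adjusted over the list alone 5 fell, among them EXT1, which polymerises the chain, and NDST1 and HS3ST3A1, which sulfate it. That count was 7 after cyclic loess and 0 after quantile normalization, and centred arrays gave 4 lower and 2 higher. Among all 680 tested genes, 210 had an unadjusted p below 0.05 for UVB by limma, so the calls alone need not set this list apart. Hyaluronan genes had a median mean IL-1α difference of 0.09 over 7 genes at percentile 98.1, which was 90.9 after cyclic loess and 91.8 after quantile normalization. The hyaluronan list's mean UVB median was -0.05, with a sign that depended on the scaling, and HAS2 was the gene called in it, over all genes tested and adjusted over the list alone. HAS1 had a mean UVB difference of -0.05, of unstable sign. HAS3 was 0.95 higher on the log2 scale with IL-1α than in sham by its brighter probe set and 0.21 by its other probe set.

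Core proteins of heparan sulfate proteoglycans, at -0.09 over 8 genes, and sialyltransferases, at -0.09 over 9, had mean UVB medians whose sign depended on the scaling, and so did keratan sulfate and small leucine-rich proteoglycans (0.03 over 5 genes), fucosyltransferases (0.09 over 8) and C-type lectins and selectins (0.06 over 17). Mean UVB medians were 0.08 over 26 glycan degradation genes, 0.07 over 31 genes of sugar nucleotide and sulfate donor supply, 0.10 over 27 N-glycan genes, 0.07 over 17 O-GalNAc genes and 0.05 over 20 galactosyl- and N-acetylglucosaminyltransferases, beside 0.07 over all tested genes. They were 0.12 over 5 galectins, 0.10 over 8 mucins, 0.04 over 15 Notch pathway genes and 0.10 over 10 adhesion molecules. The sizes depended on the scaling. N-glycan genes were at 0.03 after cyclic loess, and at 0.25 with centred arrays, where galectins were at 0.27 and all tested genes at 0.22. As deposited, all these lists lay within the central 95% of matched random lists, and glycan degradation lay outside it after quantile normalization, at 0.18 and percentile 98.1. Their mean IL-1α medians were small: -0.12 for donor supply, -0.14 for core proteins of heparan sulfate proteoglycans, -0.04 for fucosyltransferases, 0.02 for galactosyl- and N-acetylglucosaminyltransferases, 0.04 for siglecs and 0.03 for mucins kept their sign under the scalings, and the others did not, among them glycan degradation (-0.11), sialyltransferases (-0.10) and N-glycan assembly (-0.10). Sizes were less stable: after cyclic loess donor supply was at -0.005 and core proteins of heparan sulfate proteoglycans at -0.05. Siglecs, which are sialic acid-binding receptors, had a mean UVB median of 0.22 at percentile 98.3 with 8 of 8 above 0. Its size depended on the scaling and was 0.37 with centred arrays. The named siglecs, CD33, SIGLEC6, MAG and SIGLEC1, lay between 5.75 and 7.18, close to the floor. The array held 14 siglecs, and the floor favours those that were higher with UVB. SIGLEC5, SIGLEC6 and SIGLEC15 reached it only on the UVB arrays, which fixed the sign of their UVB differences. With values below the floor raised to it, their mean UVB differences were 0.11, 0.15 and 0.04. SIGLEC5 and SIGLEC15 were named after their values were seen. Over all genes tested, ST3GAL1 was the UVB call in these lists. Adjusted over the list alone, ST3GAL1, UAP1, GALNT4, OGT, NOTCH2 and LFNG fell and LUM, C1GALT1C1, LGALS9 and HES1 rose. The list counts were 0 for the donor supply list after cyclic loess and quantile normalization, 0 for galectins after cyclic loess and 0 for galactosyl- and N-acetylglucosaminyltransferases after quantile normalization, and with centred arrays they were up to 7 higher and up to 4 lower per list.

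UVB together with IL-1α left 12 genes at least 2-fold higher and 19 at least 2-fold lower than sham, a split that was 13 and 12 with centred arrays. CXCL2 stood 37.3-fold above sham, CXCL3 22.7-fold and CCL20 at least 16.2-fold, and JUNB was 4.69-fold higher. PDGFA was 4.20-fold lower, ST3GAL1 2.90-fold, CHST3 2.84-fold and HAS2 2.75-fold lower. Of the 28 genes at least 2-fold higher with IL-1α alone, 10 were still at least 2-fold above the same sham array, and 3, CXCL1, CXCL2 and CXCL3, stood above the IL-1α array, CXCL1 by 0.07 on the log2 scale, a value that turned sign under another scaling. The other 25 lay below the IL-1α array, 19 of them at least 2-fold, and CXCL5 by a log2 difference of -0.14 that turned sign with centred arrays.

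On the log2 scale the combination stood below the sum of its parts for interleukins and many chemokines. Among adhesion molecules VCAM1 and ICAM1 did so. A sum on that scale is a product of fold changes. The non-additive term was at most -1 for 20 genes and at least 1 for 2, and it was lowest for VCAM1 (-2.74), LIF (-2.47), IL1A (-2.38), CCL7 (-2.24), CSF2 (-2.08) and CCL8 (-1.88, or -1.67 with its sham value raised to the floor). VCAM1 had log2 values of 6.52 in sham, 9.22 with IL-1α, 6.20 with UVB and 6.17 with both, and ICAM1 had 11.60, 13.08, 10.98 and 11.03. BDNF (1.26) and BMP4 (1.07), which differed from sham by -0.93 and -1.22 with IL-1α alone, were the 2 genes at 1 or more. All 28 genes higher with IL-1α had a term below 0, and 19 were at most -1, although these genes were picked on the IL-1α array, which enters the term with a minus sign. Among them were CXCL2 and CXCL3, whose fold changes with both treatments exceeded the sum of those with each treatment alone. Chemokines had a median term of -0.38 and interleukins and inflammatory cytokines of -1.33, both at percentile 0 of matched random lists, and growth factors had -0.10, also at percentile 0. With centred arrays these medians were -0.21 over 29 tested chemokines, -1.29 and -0.05, at percentiles 0, 0 and 0.03. Adhesion molecules as a list did not stand below the sum, with a median term of 0.09 at percentile 85.6 and 7 of 10 above 0. No test of the term exists with 1 array per group.

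**Figure D3:**
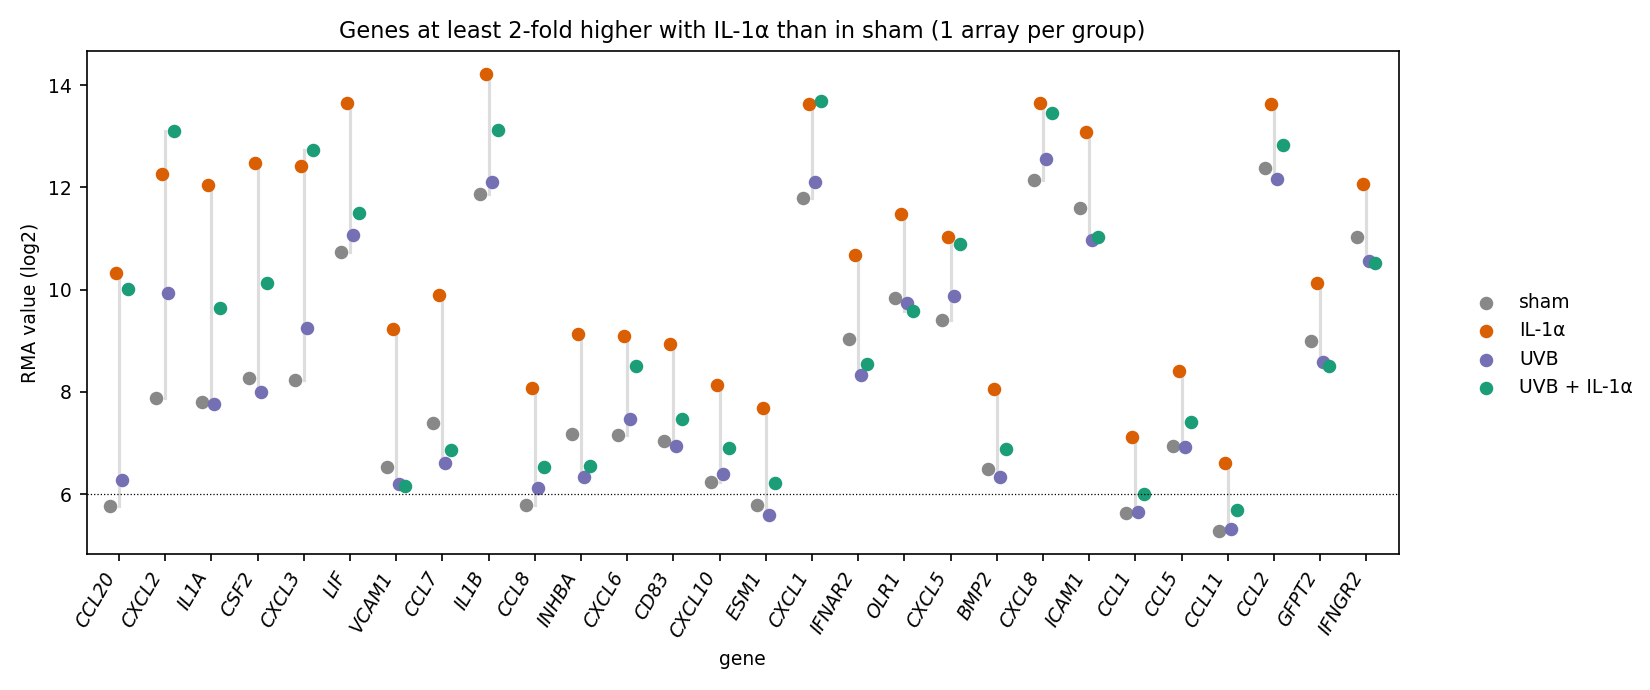
Log2 RMA values (y axis) of the 28 genes at least 2-fold higher with IL-1α than in sham (x axis, ordered by that difference), with 1 point per array coloured by group and a dotted line at the expression floor of 6. The UVB with IL-1α array lies near the IL-1α array for CCL20 (10.02 and 10.32), CXCL1 and CXCL8 and near the UVB array for VCAM1 (6.17 and 6.20), CCL7 and ICAM1.

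Fibroblast markers, 5 tested, had a median mean UVB difference of -0.02 with a sign that depended on the scaling; adjusted over the list alone PDGFRA fell, and DCN and LUM rose, a count of rises that was 1 after cyclic loess. Their median mean IL-1α difference was -0.16 at percentile 9.19 and their median non-additive term 0.24 at percentile 99.8. Endothelial markers, 4 tested, had a mean UVB median of 0.11 at percentile 64.4, of a size that depended on the scaling (0.26 at percentile 59.9 with centred arrays). Leukocyte markers, 3 tested, had 0.22, with CD33 rising adjusted over the list alone, which cyclic loess removed, from a sham value of 6.01, near the floor. The keratinocyte marker tested was LGALS7, at a mean UVB difference of 0.12 and log2 values from 6.19 to 6.39. GDF15 was the gene tested of the p53 list, at a mean UVB difference of 1.00 (adjusted p = 0.0994 by limma over all genes tested), so it was not called; a list of 1 gene leaves nothing to adjust over the list alone. GUSB was the reference gene tested, at a mean UVB difference of 0.08. Of the lists of matrix proteins and metalloproteinases and of melanocyte markers, 0 genes were named on the array.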

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

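The tests of explanations in this part were all chosen after the results they bear on were seen, and the differences between backgrounds were not tested, since each group is 1 array.

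In 6 of the 124 tested genes named by the rule, the difference with one treatment had opposite signs with and without the other and reached 2-fold in at least one background. The rule takes the genes with the lowest non-additive terms, VCAM1, LIF and CCL8 among them, so this count is no separate result. Genes outside the rule were not searched. With IL-1α, VCAM1 differed by 2.70 without UVB and -0.03 after it (non-additive term -2.74), GFPT2, an enzyme of hexosamine synthesis, by 1.14 and -0.07 (-1.20), and OLR1, a receptor for oxidised lipoprotein, by 1.64 and -0.15 (-1.79). The value after UVB turned to 0.01 for VCAM1 with centred arrays and to 0.02 for GFPT2 after cyclic loess, so its sign is not settled for these genes. With UVB, IL1B differed by 0.22 without IL-1α and -1.11 with it (-1.33), LIF by 0.32 and -2.15 (-2.47), and CCL8 by 0.34 and -1.55 (-1.88), with the same signs under the 3 scalings. The sham value of CCL8 lies below the expression floor, and the difference without IL-1α is 0.12 with that value raised to the floor.

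Smaller IL-1α differences after UVB were weighed first. Picking genes on the IL-1α array is argued against as the whole cause. Of the genes picked on the arrays it does not share, 9 of 9 had a larger log2 difference without UVB. Their median non-additive term was -0.91 and their highest -0.23, for CXCL1. Compression of the whole log2 scale on some arrays was not seen in the deposited values, whose standard deviations were alike, from 2.73 to 2.75. Normalization between arrays tends to make them alike, so this does not argue against compression before it. Flattening of the brightest values alone was not tested. The median term of the 28 genes was -1.26 after quantile normalization and -1.31 after cyclic loess, beside -1.26 as deposited. These scalings had little left to change, so they cannot speak to compression before or during the authors' normalization. A weaker IL-1α stimulus in the co-treated culture, whose dose is not given, cannot be told apart from an effect of UVB: 0 genes stood above the IL-1α array without also being higher with UVB alone, though the fraction of the difference kept ran from -0.09 for OLR1 to 0.87 for CXCL1. A hypothesis that stays open is that UVB may limit the response to IL-1α unevenly across genes; replicate cultures given a stated IL-1α dose with and without UVB would test it.

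Genes 2-fold lower with UVB in both backgrounds were weighed second. A trend with brightness left between the deposited arrays is argued against as the whole cause. Of the 7 genes, 7 were still 2-fold lower in both backgrounds after cyclic loess and 5 after quantile normalization. The deposited values were already normalized, and cyclic loess moved HAS2 only from -1.94 to -1.97. These scalings therefore cannot speak to a trend before or during the authors' normalization. Handling or batch that follows UVB cannot be told apart from UVB: the UVB arrays correlated most closely, with r of 0.995 against 0.993 for the next pair, and both explanations predict this. An effect of UVB on these transcripts remains a hypothesis, which replicate cultures handled in mixed order would test.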

How the results depend on the processing

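No paired analysis was possible because every array is number 1 of its group and each group has 1 array. Leaving out an array leaves the additive model no residual degree of freedom; the model without the other treatment would keep 1, and leaving out arrays was not run there. Total counts by size, both directions together, stayed within 1.5 times under every floor, scaling and probe set choice. By direction some moved further: genes lower with UVB than in sham went from 14 to 9 after quantile normalization, genes lower with both treatments than in sham from 19 to 12 with centred arrays, genes lower with IL-1α than in sham from 2 to 1 after cyclic loess and after quantile normalization, and genes higher with UVB in both backgrounds from 1 to 2 with centred arrays, after quantile normalization and with every probe set on its own. Totals moved with the size threshold by its construction. At 1.5-fold they were 46 for IL-1α against sham, 58 for UVB against sham, 73 for both treatments against sham, 77 for both against IL-1α, 15 for both against UVB, 47 for the non-additive term and 39 for UVB in both backgrounds. At 3-fold they were 19, 6, 8 and 15 for the first 4 of these, 8 for the non-additive term and 4 for UVB in both backgrounds. IL-1α counts in both backgrounds stayed within 1.5 times at each threshold.

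The limma calls for UVB, 9 as reported, were 23 with a floor of 5 and 23 without a floor (1 higher, 22 lower), 18 with the mean of probe sets, 49 with a trended, robust prior, and 17 without IL-1α in the model. All 9 genes were among the calls in each of these except the last, which shared 4. They were 222 with centred arrays, including the 9, and 0 after cyclic loess and 0 after quantile normalization. For IL-1α, 0 as reported, they were 13 with centred arrays and 1 without UVB in the model. The cause was not tested. The log2 differences of the 7 UVB calls named by the rule kept their direction under the 3 scalings and with the mean of probe sets; the floors and the other limma settings leave them as they are by construction. Of 84 pairs of list and effect, 11 lay outside the central 95% (4.2 by chance), and 9 to 12 under the alternatives. The 247 genes below the floor are limited by signal over background: their differences had a median size of 0.10 for UVB against sham, and a change in them could be missed.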

Other observations

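The values in this part were all chosen after they were seen. IFNGR2, an interferon receptor chain, had log2 values of 11.02 in sham, 12.07 with IL-1α, 10.56 with UVB and 10.53 with both, and the brighter probe set of IFNAR2, another, had 9.03, 10.67, 8.33 and 8.54. The other IFNAR2 probe set had 6.30, 6.70, 6.59 and 6.48, so the 2 probe sets differed in their response. The activin subunit genes went apart with IL-1α: INHBA differed from sham by 1.97 and INHBB by -0.93, and with both treatments they differed by -0.62 and -1.48. BMP2 and BMP4 also went apart, at 1.57 and -1.22 with IL-1α.

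Probe sets of 1 gene differed most for NRG1, which encodes neuregulin growth factors. Its brightest probe set, which stands for the gene elsewhere, had a mean UVB difference of -0.37, another -0.97 and the dimmest -3.16, with log2 values of 8.34 in sham, 9.32 with IL-1α, 5.62 with UVB and 5.73 with both. The UVB values lie below the expression floor, and the difference is -2.83 with them raised to the floor. For CXCL12, a chemokine of stromal cells, 1 probe set had a mean UVB difference of 0.35 and another -0.62. Among 70 genes with at least 2 probe sets above the floor, the mean UVB difference ranged over more than 1 on the log2 scale in 2 genes, and the median range was 0.10.

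Of the 123 unnamed probe sets above the floor, 6 were at least 2-fold lower and 0 higher with UVB than in sham, and 5 were lower and 0 higher with both treatments than with IL-1α.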
